A study of Mus musculus with 16 samples.

How the data were processed

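Liver RNA of mice was measured on 16 expression arrays, 1 array for each of 4 arms at days 0, 2, 7 and 14 after partial hepatectomy (removal of part of the liver, after which the rest grows back). MET_FLOX mice carried a Met gene flanked by recombination sites, and in MET_KO mice exon 16 of Met had been deleted with an inducible recombinase. MET_FLOX_canertinib and MET_KO_canertinib mice also received a diet with canertinib, an inhibitor of the EGFR receptor family, aimed at 80 mg/kg. Nothing in the labels states whether an array holds RNA of 1 animal or of a pool, so p-values measure the spread between these arrays.

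The deposited values are MAS5 signal intensity per probe set on a linear scale, from 6 ug of total RNA per the labels. The MAS5 version is not given in the sources used here. In every array the mean signal without the lowest and highest 2% of probe sets was 500, which is the scaling the authors applied. Detection calls were not used here. No replicate array exists for an arm at a day, so no p-value measures the spread between livers of an arm at a day.

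Of 45101 probe sets, 64 control probe sets were left out. A single gene was annotated for 34945 probe sets, 932 named several genes and 9160 named none, and only the first kind was used. The log2 of the signal plus 16 was taken. Probe sets were kept where at least 4 of the 16 arrays lay above their own array's median, which left 26866. The probe set with the highest mean stood for its gene, giving 13577 genes.

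Genes were tested with limma 3.58.1 in R 4.3.3, with arm and day as terms, moderated variances with an intensity trend and 9 residual degrees of freedom. Each arm thus held 4 arrays, with day as a block, and each day held 4 arrays, with arm as a block. Genes with a Benjamini-Hochberg adjusted p below 0.05 in a two-sided test were called. The comparisons were canertinib arms against arms without it, knockout arms against flox arms, 5 pairs of arms, the genotype by canertinib interaction, days 2, 7 and 14 against day 0, and the difference in day 2 response between MET_KO_canertinib and MET_FLOX, which had 6 residual degrees of freedom. A day 2 response was day 2 minus the mean of days 0, 7 and 14. Arm minus arm is printed so that a positive log2 difference is higher in the arm named first. Errors are standard errors of the model, whose spread is what arm and day as separate terms leave over. An arm's own course over the days thus counts as error.

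The array medians fell into 2 separate sets, which no label names. A low set of 6 arrays held MET_FLOX and MET_KO at days 0, 2 and 7, and a high set of 10 held all other arrays, parted here at a median signal of 216.35. After this was seen, every comparison was also fitted with the array set as a term, which left 8 residual degrees of freedom. In that model a canertinib difference is the difference at day 14 alone, since the 4 arrays of day 14 all lie in the high set. Comparisons of genotypes and the interaction are balanced over the sets and keep their estimates.

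33 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. They covered DNA replication and S phase, G2/M and mitosis, p53 targets and CDK inhibitors, MET and EGFR ligands with receptors and adaptors, ERK-responsive genes, bile acid synthesis and transport, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation with PPAR alpha targets, the urea cycle with amino acid breakdown, xenobiotic cytochromes P450, NRF2 and glutathione genes, hepatocyte transcription factors with secreted proteins, the acute phase response, inflammatory cytokines and chemokines, ER stress, apoptosis regulators, ribosome biogenesis, the growth hormone and IGF axis, male-biased and female-biased liver genes, circadian clock genes, pericentral and periportal hepatocyte markers, and markers of Kupffer cells and macrophages, neutrophils, lymphocytes, endothelium, stellate cells and matrix, cholangiocytes and progenitors, erythroid cells and blood, pancreatic acinar cells and adipocytes.

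A list score was the mean over its measured genes of the log2 value centred on the gene's mean over the 16 arrays. Scores were compared by exact two-sided permutation of arm labels within each day, with 1296 allocations for 2 arms against 2 and 256 for 1 arm against 3, and of day labels within each arm with 256 allocations. Benjamini-Hochberg adjustment ran over 99 tests by arm and 132 by day. Lists were also tested in the limma fits with camera, using a preset correlation between genes of 0.01 and an estimated one, and with fry. These p-values were adjusted over the 33 lists within each comparison. Median differences of lists between single arrays were set against 10000 random lists of the same size matched in 10 expression bins.

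The genes named were the 8 with the largest rise and the 8 with the largest fall among called genes with the same direction at all 4 days (or in all 4 arms). From each list up to 4 called members with the largest difference were added, or, where none was called, up to 2 with the smallest p, given as values. For MET_KO_canertinib against MET_FLOX at day 2 the 8 largest rises and falls between the single arrays were given without a test. Met, Egfr, Hgf, Ccnd1, Ccna2, Ccnb1, Cdk1, Mki67, Pcna, Cdkn1a, Cyp7a1 and Alb were given by array. Ccnb1 had no probe set annotated to it alone. Other genes named, such as those with the smallest p or called with the array set as a term, were chosen after their values were seen.

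The alternatives were quantile normalization, centring each array on its median, a pseudocount of 1 or 64, no filter or a stricter one at the 75th percentile, the mean of a gene's probe sets, every probe set by itself, only the arms or days compared, no block, array weights, no intensity trend, the median as list score, and leaving out each array, each day and each arm. Chosen after seeing the data were the array set as a term, the same after quantile normalization or without the MET_KO_canertinib day 14 array, fry, sign flips of genotype pairs within an array set, day 2 minus day 0 within each arm, and the day 2 response against the mean of the other 3 arms.

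The models were tested on simulated data with 13577 genes, of which 100 changed by 1 and another 100 by 2 on the log2 scale. For canertinib 68 genes changed by 1 and 93 changed by 2 were recovered. With a simulated array set and no term for it, 2029 unchanged genes were called. With the term, 5 genes changed by 1 and 50 changed by 2 were recovered. Recovery at a change of 1 and of 2 was 29 and 84 genes for MET_KO against MET_FLOX, 6 and 58 for the interaction, and 43 and 82 for day 2 against day 0.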

Results

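The question addressed was how the regenerating liver's transcripts differ when the growth factor receptors MET and EGFR are blocked alone or together. Met, which encodes the receptor of hepatocyte growth factor, gave signals of 1577, 1418, 1962 and 1041 in MET_FLOX at days 0, 2, 7 and 14, and of 2066, 1618, 2036 and 1011 in MET_KO. With canertinib it gave 1118, 1165, 2014 and 1264 in MET_FLOX_canertinib and 1421, 982, 1285 and 1321 in MET_KO_canertinib. The other Met probe set lay between 98 and 700. Where these probe sets lie relative to the deleted exon 16 is not given in the sources used here, so they do not check the deletion. Egfr, the receptor that canertinib inhibits, ranged from 2764 to 12541 over the arrays, and Hgf, the ligand of MET, from 145 to 683.

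The called genes with the largest rise at day 2, when hepatocytes divide after the operation, included genes of mitosis. Over the 4 arms Birc5, which acts in chromosome segregation and cell survival, rose by 4.67 on the log2 scale (SE 0.56, adjusted p = 0.00435). Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, rose by 4.15 (SE 0.54), and Cdk1, the kinase that starts mitosis, by 4.05 (SE 0.47, adjusted p = 0.00435), each in 4 of 4 arms. At day 0 Birc5 gave 48, 19, 45 and 48, far under the array medians of 176.8 to 251.3. Ube2c and Cdk1 lay under these medians outside MET_FLOX. The sizes of these 3 rises thus depend on the pseudocount. Top2a, Uhrf1, Rrm2, Mcm2 and Pcna, which serve DNA replication and its chromatin, rose by 2.92, 3.08, 2.62, 2.27 and 2.17. Ccnd1, the cyclin induced by growth factors at the start of the cycle, rose by 1.87 (SE 0.28, adjusted p = 0.0121). The genes that fell were fewer. Agps, an enzyme of ether lipid synthesis, changed by -1.91 (SE 0.34, adjusted p = 0.0269), Leap2, a secreted hepatocyte peptide, by -1.34, Flcn by -1.30, and the glycolytic regulators Pdk1 and Pklr by -1.21 and -1.18.

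In all, 45 genes rose and 7 fell between days 0 and 2 over the 4 arms, and 23 of the 45 belonged to the S phase or G2/M lists. In the G2/M list 16 of 31 genes were called higher, and 24 when adjusted over the list alone. In the S phase list 7 of 31 were called higher, and 27 higher with 1 lower when adjusted over the list alone. The list scores of day 2 exceeded those of the other days by 1.61 for G2/M and 1.41 for S phase in 4 of 4 arms. The exact two-sided permutation p was 0.003906 for both, the smallest these permutations can give, and 0.129 after adjustment over 132 tests. With camera the adjusted p was 0.0591 for G2/M and 0.0758 for S phase with an estimated correlation. The count of 52 genes was 61 with the array set as a term, of which 47 were shared. It was 0 without the MET_KO or the MET_FLOX_canertinib day 2 array, 3 without the MET_FLOX day 2 array, 15, 4 and 10 without the day 0 arrays of these arms in the order MET_FLOX, MET_KO and MET_FLOX_canertinib, 94 without the MET_KO_canertinib day 14 array and 171 without its day 2 array.

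The cell cycle genes moved least in the arm in which both receptors were targeted. Day 2 minus day 0, the 62 genes of the S phase and G2/M lists changed by a median log2 of 2.06 in MET_FLOX, 2.73 in MET_KO, 1.55 in MET_FLOX_canertinib and 0.37 in MET_KO_canertinib. Of these genes 52 had their smallest change in MET_KO_canertinib, and 10 changed there by more than 1, against 50, 52 and 44 in the other arms. Pcna, the replication clamp, reached 9267, 10301 and 5420 at day 2 in MET_FLOX, MET_KO and MET_FLOX_canertinib and 1461 in MET_KO_canertinib, where it stood at 1294 at day 0. Mki67, a proliferation marker, gave 1690, 2839, 1496 and 101 at day 2 in the same order. Cdk1 gave 3234, 4354, 2432 and 550, Ccna2, a cyclin of S phase and mitosis, 1657, 2306, 2034 and 745, and Ccnd1 6256, 8099, 5404 and 2124. Cdkn1a, a cell cycle inhibitor, ranged from 318 to 1870 over the 16 arrays. Both day 0 and day 2 arrays of an arm lie in the same array set. Genes outside these lists also moved little in MET_KO_canertinib. For 200 of them, chosen by their change in the other arms, the slope was 0.171. It was 0.54, 0.772 and 0.518 in MET_FLOX, MET_KO and MET_FLOX_canertinib. The MET_KO_canertinib array also had the highest Gapdh 3' to 5' ratio of the day 2 arrays (1.35, others up to 1.11).

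**Figure D1:**
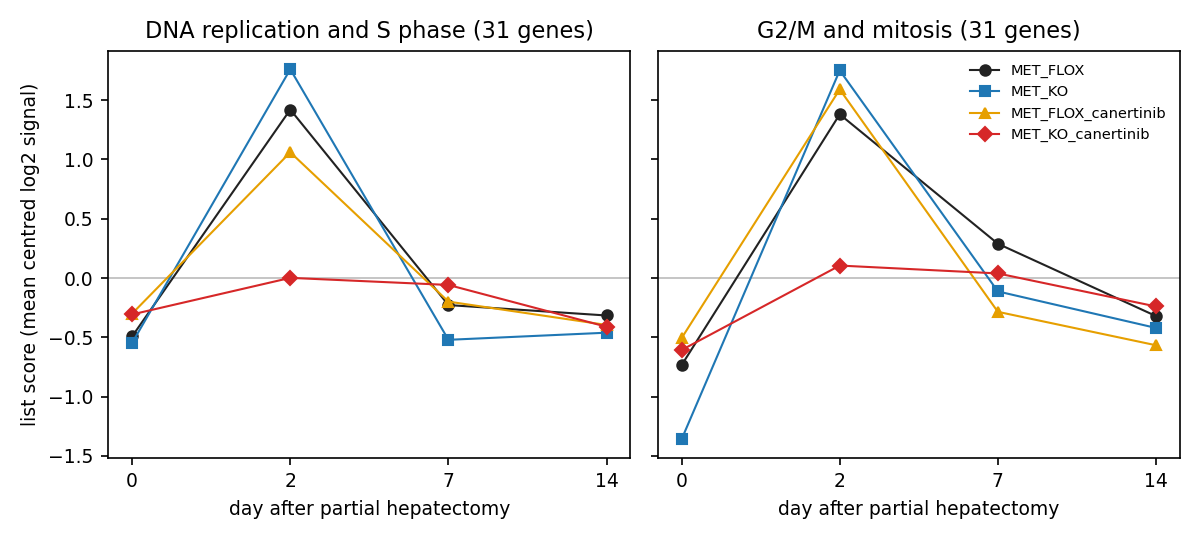
Mean score of the S phase and G2/M gene lists (log2, centred per gene over 16 arrays) on the vertical axis against days after partial hepatectomy on the horizontal axis, 1 point per array and 1 line per arm. At day 2 the S phase score was 1.42 in MET_FLOX, 1.76 in MET_KO, 1.06 in MET_FLOX_canertinib and 0.00129 in MET_KO_canertinib.

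A test of the day 2 response itself, MET_KO_canertinib against MET_FLOX, called 0 genes with limma and gave 677 at an unadjusted p below 0.05, where 679 arise by chance. It compares 1 array for each arm and day, so its spread comes from the other arms and days and does not measure that between livers of this arm at day 2. The smallest p-values among cell cycle genes belonged to Rrm2, which makes deoxynucleotides, at -2.48 (SE 0.41, adjusted p = 0.331), Top2a at -2.98 (adjusted p = 0.373) and Mcm3 at -2.49 (adjusted p = 0.62). In the S phase list the mean difference in response was -1.50, and 16 of 31 genes were lower when adjusted over the list alone. Camera gave the S phase list an adjusted p of 0.0078 with an estimated correlation, and fry one of 0.00304. For G2/M the mean was -1.26, 2 genes were lower when adjusted over the list alone, and the adjusted p was 0.182 with an estimated correlation. Against the mean of the other 3 arms, a contrast chosen after seeing the data, Top2a (-3.63), the septin gene Septin3 (-3.08) and Rrm2 (-2.60) had an adjusted p of 0.0338. All of these rest on 1 day 2 array of MET_KO_canertinib.

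Between the single day 2 arrays of MET_KO_canertinib and MET_FLOX the largest rises included Moxd1 (5.66), the metallothioneins Mt1 (5.13) and Mt2 (4.77), which bind zinc, Rbpjl (4.59) and Cyp8b1 (4.49), a bile acid synthesis enzyme. The largest falls included Tubb6, a tubulin, at -5.31, Ptgr1 at -4.59, Ect2, a regulator of cytokinesis, at -4.46, and Nuf2, a kinetochore gene, at -4.03. The size of these differences depends on the pseudocount where a signal is low, as for Moxd1 (17 in MET_FLOX) and Tubb6 (24 in MET_KO_canertinib), far under the array medians of 168.8 and 246.3. These carry no test and cross the array sets, where the median of all genes differed by 0.26. The median difference was -1.38 in the S phase list, with 4 of 31 genes higher, and 1.77 in the neutrophil list, with 11 of 11 higher. Other lists were higher as well, with medians of 1.60 for adipocyte, 1.54 for acinar, 1.38 for cytokine, 1.36 for acute phase, 1.19 for lymphocyte and 1.12 for erythroid genes.

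With Met deleted alone, as the arms are labelled, no gene passed the threshold. MET_KO against MET_FLOX called 0 genes with limma (350 at an unadjusted p below 0.05), and both knockout arms against both flox arms called 0 (322 at an unadjusted p below 0.05, with 679 by chance). With the array set as a term the counts were again 0, with 516 and 520 at an unadjusted p below 0.05. MET_KO against MET_FLOX was 1 without the MET_FLOX_canertinib day 7 array and 2 without the MET_FLOX day 14 array. Given as values, Acad10, an acyl-CoA dehydrogenase, differed by 1.82 (SE 0.30, adjusted p = 0.279), Mmd2 by -3.40 (SE 0.60, adjusted p = 0.349), and Hsd3b5, a steroid dehydrogenase of the male mouse liver, by 5.27 (SE 1.06, adjusted p = 0.575), each the same way at 4 of 4 days. The size for Hsd3b5 depends on the pseudocount, with signals of 54, 9, 9 and 1271 in MET_FLOX. Over both diets, the pericentral hepatocyte list differed by -0.19 in the knockout arms, at 4 of 4 days, with an exact permutation p of 0.0463 and 0.258 after adjustment over 99 tests. The difference was -0.186 in the low array set and -0.190 in the high one.

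As the arms are labelled, the genotype difference depended on the drug in Cyp17a1, which encodes a steroid 17-alpha-hydroxylase that is higher in female mouse liver. Exchanged genotype labels in the arms without canertinib could give the same picture, as described further below. The signals of Cyp17a1 at days 0, 2, 7 and 14 were 2563, 3559, 1976 and 602 in MET_FLOX and 557, 723, 413 and 388 in MET_KO. With canertinib the order was the other way, with 268, 661, 592 and 778 in MET_FLOX_canertinib and 3264, 4258, 6125 and 7073 in MET_KO_canertinib. The interaction was 4.99 on the log2 scale (SE 0.62, adjusted p = 0.011), positive at 4 of 4 days. Mmd2, a membrane protein of the progestin receptor family, had an interaction of 6.56 (SE 0.85, adjusted p = 0.011), with signals of 5754, 5642, 4476 and 806 in MET_FLOX, 316, 361, 499 and 135 in MET_KO, 677, 774, 90 and 494 in MET_FLOX_canertinib and 3594, 4241, 9085 and 1350 in MET_KO_canertinib. Both estimates were the same with the array set as a term, at adjusted p-values of 0.000568 and 0.0187. Hsd3b5 had the opposite course, at -8.67 (SE 1.50, adjusted p = 0.112), which is given as a value only and depends on the pseudocount, since some signals were as low as 9.

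**Figure D2:**
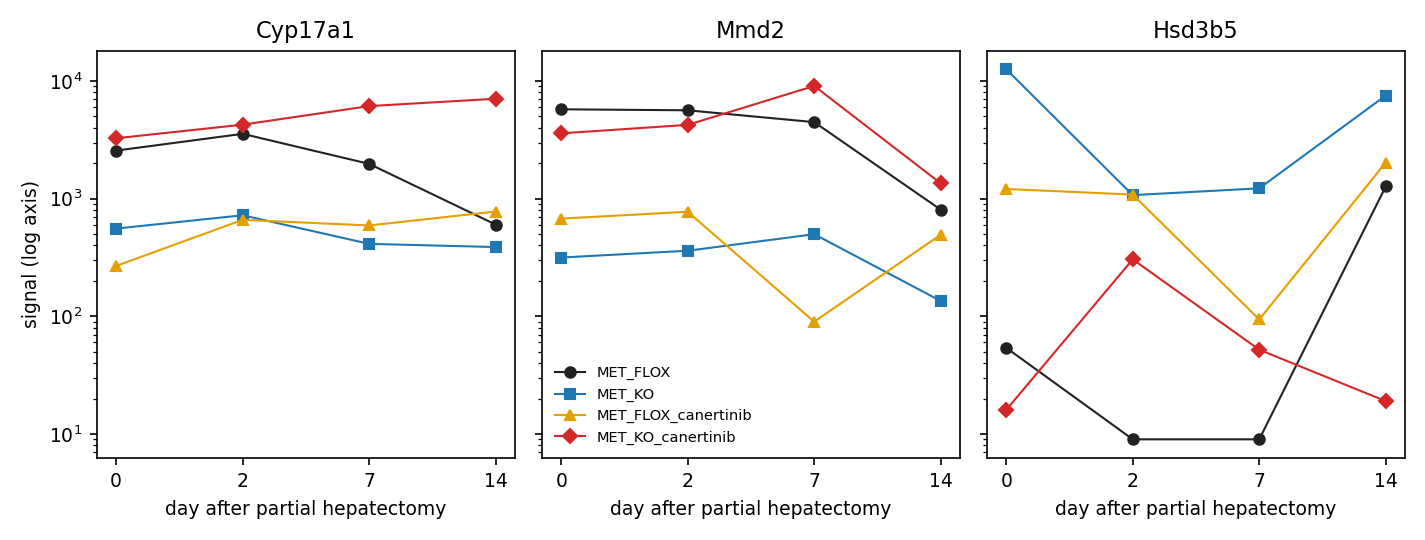
Signal of Cyp17a1, Mmd2 and Hsd3b5 on a log vertical axis against days after partial hepatectomy, 1 point per array and 1 line per arm. At day 7 the signal of Cyp17a1 was 6125 in MET_KO_canertinib and 592 in MET_FLOX_canertinib, and that of Hsd3b5 was 52 and 94.

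These were the 2 genes called for the interaction with limma, of 601 at an unadjusted p below 0.05. The count was 0 without MET_FLOX day 0, 2 or 7 or MET_KO day 2, 1 without MET_KO day 0, 3 without the day 0 or 14 array of MET_FLOX_canertinib or the day 2 array of MET_KO_canertinib, 4 without MET_FLOX day 14 or MET_KO_canertinib day 7, and 5 without MET_KO_canertinib day 14. Under the drug, MET_KO_canertinib against MET_FLOX_canertinib called 1 gene, again Cyp17a1, at 3.17 (SE 0.44, adjusted p = 0.0485, and 0.002 with the array set as a term). The count was 0 without any single array other than MET_FLOX days 0 and 14 and MET_FLOX_canertinib day 14. Cyp7b1, an oxysterol hydroxylase that is higher in male liver, differed by 1.68 and the hepatocyte factor Foxa3 by -1.01, neither called. Across all genes the genotype difference without canertinib and that with it had a Pearson r of -0.147 and a Spearman rho of -0.102. Genes are not independent replicates in these correlations.

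Between the canertinib arms and the arms without it, single genes of the acute phase and of neutrophils were higher, while their lists did not pass by permutation (adjusted p = 0.194 and 0.0764). Lcn2, an iron-binding protein of neutrophils and inflamed hepatocytes, differed by 2.23 (SE 0.67, adjusted p = 0.022) over 8 arrays against 8, Saa3, an acute phase protein, by 2.003 (SE 0.38, adjusted p = 0.00366), the neutrophil granule gene Ngp by 1.20 (SE 0.22, adjusted p = 0.00324) and the neutrophil chemokine Cxcl2 by 1.64 (SE 0.38, adjusted p = 0.00701). Mt1 and Mt2 differed by 2.78 and 2.62, the lymphocyte genes Cd8a and Ms4a1 by 1.09 and 1.12, and Alb, the main plasma protein of hepatocytes, by 1.23 (SE 0.23). Alb ranged from 18701 to 117413. Lower were Gstp3, a glutathione transferase, at -2.76 (SE 0.36, adjusted p = 0.00157), the cholesterol synthesis genes Mvk (-1.78), Msmo1 (-1.41), Fdps (-1.36) and Idi1 (-1.09), the bile acid importer Slc10a1 (-0.87, SE 0.18, adjusted p = 0.00459), the lipogenic genes Me1 (-0.93) and Fasn (-0.82), and Nadk2, the mitochondrial NAD kinase, which had the smallest p of all genes (-1.34, SE 0.12, adjusted p = 0.000146).

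These differences mix the drug with the array set. A sign of RNA quality moved with the drug too, as the Gapdh 3' to 5' ratio was 0.950 to 2.24 in the canertinib arrays and 0.765 to 0.869 in the others, and 1.13 and 2.24 against 0.811 in both at day 14. Of 4699 called genes 3255 were higher and 1444 lower, with a median of all genes of 0.143. A term for the array set left 15 genes called, 9 of them shared, with 1706 at an unadjusted p below 0.05. Its estimates rest on the 4 arrays of day 14 and are less precise (median SE 0.334 against 0.191), which by itself lowers the count. Of the called genes 69.3% were higher as deposited, 39.8% after centring each array on its median, which moved the median of all genes to -0.063, and 51.6% after quantile normalization. The count was 1706, 595, 1042 and 6405 without days 0, 2, 7 and 14. At day 14, where all 4 arrays lie in the same set, Lcn2 differed by 1.96, Saa3 by 1.84, Ngp by 1.46 and Cxcl2 by 1.68, while Alb differed by 0.44, Ms4a1 by 0.00, Msmo1 by 0.30, Idi1 by 0.01 and Nadk2 by -1.26, none called by limma. The first 4 values lean on the MET_KO_canertinib array, since the signals in MET_FLOX, MET_KO, MET_FLOX_canertinib and MET_KO_canertinib were 10112, 4172, 7616 and 83663 for Lcn2 and 3715, 812, 1528 and 25464 for Saa3, so that the flox pair went the other way in both. Past the threshold at day 14 were 15 genes that include Slc10a1 (-1.69, adjusted p = 0.021), Me1 (-2.14, adjusted p = 0.021), which makes NADPH for lipogenesis, the deubiquitinase Usp15 (-3.07, adjusted p = 0.00335), the fatty aldehyde dehydrogenase Aldh3a2 (-1.997, adjusted p = 0.00712), the glutathione transferase Gsta3 (-2.76, adjusted p = 0.04) and the retinol dehydrogenase Rdh16 (-1.53, adjusted p = 0.0402).

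In MET_FLOX_canertinib against MET_FLOX genes of cholesterol and bile acid synthesis were among those called, though no list passed with an estimated correlation or with fry. Msmo1, a sterol oxidase, differed by -2.16 (SE 0.58, adjusted p = 0.043), Fdps by -2.11, Idi1 by -1.76, Cyp7b1 by -1.80 (SE 0.40, adjusted p = 0.0323) and Cyp17a1 by -1.73 (adjusted p = 0.0403). The sodium-calcium exchanger Slc8a1 was higher by 3.36 (SE 0.54, adjusted p = 0.0152) and the plasma lipoprotein Apoa1 by 1.39. Called were 548 genes higher and 363 lower (248 and 794 after centring each array on its median, 144 and 228 after quantile normalization), and 9 with the array set as a term, 1 of them shared. In the cholesterol list 5 of 19 were called lower and 13 when adjusted over the list alone, with a mean of -1.09, and of -0.25 with the array set as a term (adjusted p = 0.768 with an estimated correlation). The count of 911 was 98, 6 and 13 without MET_FLOX days 0, 2 and 7, 21, 25 and 10 without the same days of MET_FLOX_canertinib, 596 and 298 without MET_KO days 0 and 7, 432 and 557 without MET_KO_canertinib days 0 and 7, 2216 without MET_FLOX_canertinib day 14 and 1587 without MET_KO_canertinib day 14.

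In MET_KO_canertinib against MET_KO single inflammation genes were among those called. Saa3 was higher by 3.57 (SE 0.54, adjusted p = 0.0147), Saa1, the serum amyloid of hepatocytes, by 2.54, Cxcl2 by 2.19 (SE 0.54, adjusted p = 0.0343), the endotoxin receptor gene Cd14 by 2.01 and Cyp17a1 by 3.26 (SE 0.44, adjusted p = 0.0144). Hsd3b5 was lower by a log2 difference of -5.58 (SE 1.06, adjusted p = 0.0193), Gsta2 by -2.25, Igfbp2 by -2.17, the bile acid importer Slc10a1 by -1.04 (adjusted p = 0.0345), the glycolate oxidase Hao1 by -1.32 and Cpt2, of mitochondrial fatty acid import, by -0.83. Signals of Hsd3b5 in MET_KO_canertinib were 16, 305, 52 and 19 at days 0, 2, 7 and 14, so its size depends on the pseudocount. With the array set as a term Cyp17a1 (4.74, adjusted p = 0.00381) and Slc10a1 (-1.86, adjusted p = 0.0326) were called. Of 25 acute phase genes 5 were called higher, and 15 when adjusted over the list alone, with a mean of 1.27 and of 1.35 with the array set as a term (adjusted p = 0.691 with an estimated correlation). The value with the term leans on the MET_KO_canertinib day 14 array, with an acute phase score of 1.41 against -0.672 in MET_KO. Called were 793 genes higher and 324 lower (367 and 876 after centring, 144 and 166 after quantile normalization), and 10 with the array set as a term, 4 of them shared. The count of 1117 was 22, 36 and 20 without MET_KO days 0, 2 and 7, 267, 17 and 219 without the same days of MET_KO_canertinib, 733 and 578 without MET_FLOX days 0 and 7, 1701 without MET_FLOX_canertinib day 14, and 2265 and 1938 without the day 14 arrays of MET_KO and MET_KO_canertinib.

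With both receptors targeted, MET_KO_canertinib against MET_FLOX gave higher Nfkbid, a regulator of NF-kappa-B (2.63, SE 0.43, adjusted p = 0.0189), Saa3 (2.28), Cxcl2 (2.28, adjusted p = 0.0413), Ngp (1.64), the fetal liver gene Dlk1 (1.38), the bile duct factor Sox9 (1.21) and the citrate importer Slc13a5 (1.29, SE 0.20, adjusted p = 0.0153). Lower were Gstp3 (-3.27, SE 0.51, adjusted p = 0.0153), Acot1, an acyl-CoA thioesterase under PPAR alpha (-2.32), Cdk1 (-1.94, SE 0.47, adjusted p = 0.046), the death receptor gene Fas (-1.29), the chemerin gene Rarres2 (-1.12) and Nadk2 (-1.46, SE 0.17, adjusted p = 0.00422). Called were 236 genes higher and 155 lower at 4 arrays against 4 (129 and 476 after centring, 48 and 97 after quantile normalization), and 5 with the array set as a term, 1 of them shared. Neutrophil genes had a mean of 1.25, and of 1.23 with the array set as a term, with 2 of 11 called and 6 when adjusted over the list alone (adjusted p = 0.645 with an estimated correlation). The value with the term leans on the MET_KO_canertinib day 14 array, whose neutrophil score was 2.14 against 0.252 in MET_FLOX_canertinib. The count of 391 was 3, 1 and 1 without MET_FLOX days 0, 2 and 7, 58, 9 and 35 without the same days of MET_KO_canertinib, 220 and 103 without MET_KO days 0 and 7, 204 and 235 without MET_FLOX_canertinib days 2 and 7, 887 without its day 14, and 1075 without MET_KO_canertinib day 14.

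The drug difference in flox and that in knockout livers, which share no array, had an r of 0.653 and a rho of 0.703 across genes, with 181 shared higher genes (32 by chance) and 113 shared lower genes (8.66 by chance). At day 14 alone, within 1 array set, r was 0.0741 and rho 0.092.

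At day 14 Rdh16 and Retsat, of retinoid metabolism, were lower than at day 0. Rdh16, a retinol dehydrogenase, differed by -1.32 (SE 0.21, adjusted p = 0.0343) and by -1.62 with the array set as a term (adjusted p = 0.0142), and Retsat, a retinol saturase, by -2.12 (SE 0.30, adjusted p = 0.0315) and by -2.40 (adjusted p = 0.0273), both in 4 of 4 arms. Pelo, of ribosome rescue, differed by -2.34 (SE 0.30, adjusted p = 0.0193), Acad11, an acyl-CoA dehydrogenase, by -1.09 and Sar1b, which acts in lipoprotein export, by -1.03. With the array set as a term Slc10a1 (-1.72, adjusted p = 0.0132), Me1 (-2.06, adjusted p = 0.0148), the peroxisomal Pex11a (-1.51, adjusted p = 0.0273) and the lipase Mgll (-1.31, adjusted p = 0.0323) were lower too, and the chemokine Cxcl14 was higher (2.34, adjusted p = 0.00891). With that term the difference comes mainly from the canertinib arms, as the others change array set at day 14. Pex11a differed by 0.16, -0.19, -1.23 and -1.94 in MET_FLOX, MET_KO, MET_FLOX_canertinib and MET_KO_canertinib, and Me1 by -0.14, -0.52, -2.58 and -1.77. The same day 14 arrays gave the canertinib differences of Slc10a1 and Me1. The fatty acid oxidation list had a mean of -0.76, with 0 of 22 called and 9 lower when adjusted over the list alone, and of -0.94 with the array set as a term (adjusted p = 0.111 with an estimated correlation). Its score at day 14 was lower than at the other days by -0.70 in 4 of 4 arms (exact permutation p = 0.003906, adjusted 0.129). Ehhadh, a peroxisomal enzyme under PPAR alpha, differed by -2.70 (SE 0.69) and the neutrophil gene S100a8 by 2.54, neither called.

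Day 14 against day 0 called 2 genes higher and 9 lower with limma (2240 at an unadjusted p below 0.05), and 27 with the array set as a term, 4 of them shared. The count of 11 was 152 without MET_FLOX_canertinib day 14, stayed 11 without MET_KO_canertinib day 7, and was between 0 and 6 without any other single array. Day 7 called 1 gene (662 at an unadjusted p below 0.05), Etfbkmt, a mitochondrial methyltransferase, at 1.64 (SE 0.16, adjusted p = 0.000817, 4 of 4 arms), with 3 and 5 genes without MET_KO_canertinib days 2 and 7. As values at day 7, the collagen gene Col3a1 differed by 1.78 (SE 0.36, adjusted p = 0.485) and the acute phase gene Orm2 by 3.44 (SE 0.70, adjusted p = 0.485). In the cholesterol list 0 genes were called and 12 of 19 were lower at day 7 when adjusted over the list alone (mean -0.84, adjusted p = 0.278 with an estimated correlation).

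At day 14, MET_KO_canertinib and MET_KO could be compared as single arrays of the same array set. The MET_KO_canertinib array stood apart from all others, with the lowest mean correlation of the 16 (0.805, median 0.873) and the highest array median (265), and every difference here rests on it. Bile acid genes had a median difference of -1.31, with 0 of 19 higher, fatty acid synthesis genes of -1.24, xenobiotic cytochromes P450 of -1.36 and male-biased genes of -1.47, with 0 of 12 higher. Acute phase genes had a median of 1.71, with 23 of 25 higher, neutrophil genes of 1.36, with 11 of 11 higher, and ER stress genes of 0.86, with 23 of 24 higher. Cytokines had a median of 0.98, Kupffer cell and macrophage genes of 0.70, with 19 of 24 higher, and cholesterol synthesis genes, unlike those of fatty acids, of 0.57, with 16 of 19 higher, while periportal genes had one of -1.32. Against MET_FLOX_canertinib at day 14 the medians were -0.80, -1.39, -0.53 and -1.77 for the first 4 lists and 1.84, 1.40 and 0.66 for acute phase, neutrophil and ER stress genes. For cholesterol synthesis genes it was only 0.13, with 11 of 19 higher. Their score at day 14 was low in MET_KO, at -0.44, against 0.494, 0.0753 and 0.211 in MET_FLOX, MET_FLOX_canertinib and MET_KO_canertinib. Cyp7a1, the first enzyme of bile acid synthesis, gave 415 in MET_KO_canertinib at day 14 against 5003, 905 and 3216 in MET_FLOX, MET_KO and MET_FLOX_canertinib. Against random lists of the same size, the medians relative to MET_KO lay at percentile 0 for the first 4 lists and 100 for acute phase, neutrophil and ER stress genes, which compares genes and does not measure the spread between livers.

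**Figure D3:**
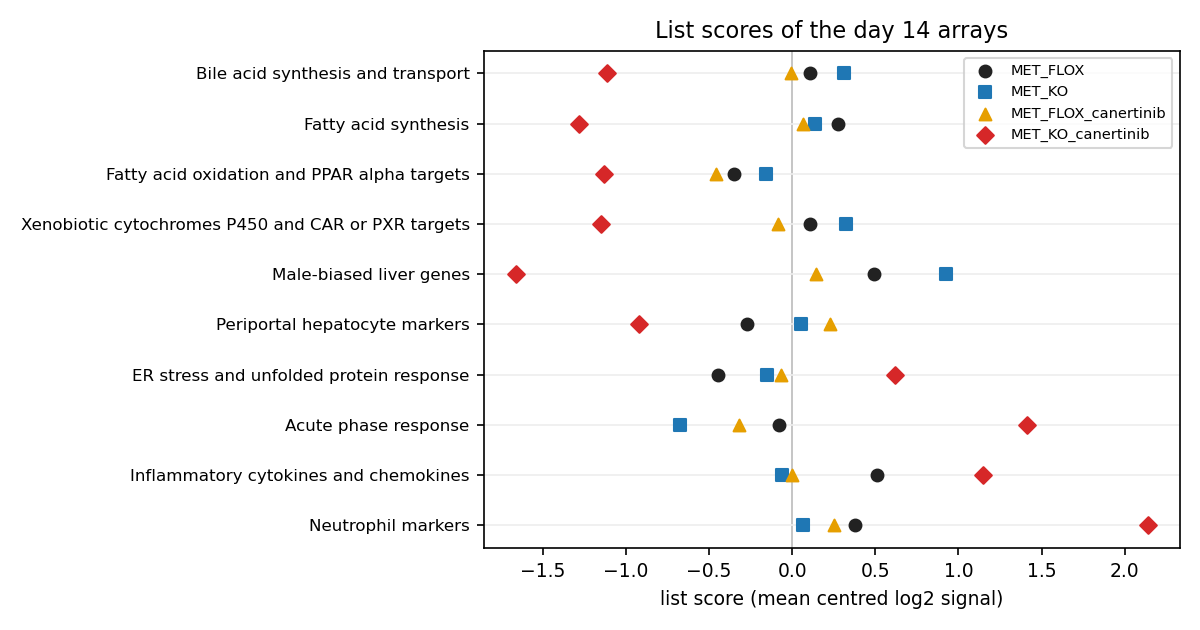
Scores of gene lists (log2, centred per gene over 16 arrays) in the 4 arrays of day 14, which lie in the same array set, 1 point per array. In MET_KO_canertinib the fatty acid synthesis score was -1.28, the fatty acid oxidation score -1.13 and the neutrophil score 2.14.

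None of the 99 list tests by arm passed the adjusted threshold, which the few allocations put out of reach of a single list. For canertinib arms minus the others, neutrophil genes differed by 0.996, lymphocyte genes by 0.62 and acinar genes of the pancreas by 0.51, each at an exact permutation p of 0.00309, and cholangiocyte genes by 0.30 at an exact permutation p of 0.00154, all with an adjusted p of 0.0764. With the array set as a term these were 0.97, 0.10, 0.12 and 0.13. That of 0.97 comes from 1 array, since the neutrophil scores at day 14 were 0.379 in MET_FLOX, 0.0669 in MET_KO, 0.252 in MET_FLOX_canertinib and 2.14 in MET_KO_canertinib. Acute phase genes differed by 0.85 (0.92 with the term; exact permutation p = 0.017), and their scores at day 14 were -0.0771, -0.672, -0.318 and 1.41 in the same order, so that the flox pair went the other way. Cholesterol synthesis differed by -0.72 (0.12 with the term; exact permutation p = 0.0201), bile acid genes by -0.40 (-0.77; exact permutation p = 0.0278), cytokines by 0.46 (0.35; exact permutation p = 0.0278), endothelial genes by -0.42 (0.00; exact permutation p = 0.0216), hepatocyte factors by 0.35 (0.10; exact permutation p = 0.0201) and erythroid genes by 0.33 (-0.04; exact permutation p = 0.0309). The remaining lists had an exact permutation p of 0.0617 or more. Without and with the term, S phase differed by -0.15 and -0.02, G2/M by -0.12 and -0.03, p53 targets by 0.16 and 0.54, MET and EGFR ligands by 0.10 and 0.12, and ERK-responsive genes by 0.23 and 0.32. Fatty acid synthesis differed by -0.38 and -0.81, fatty acid oxidation by -0.27 and -0.54, the urea cycle by -0.21 and -0.34, cytochromes P450 by -0.25 and -0.83, and NRF2 genes by 0.03 and -0.25. ER stress genes differed by 0.01 and 0.57, apoptosis regulators by 0.11 and 0.14, ribosome biogenesis by -0.05 and 0.38, and growth hormone genes by 0.13 and 0.17. Male-biased genes differed by -0.45 and -1.47, female-biased genes by 0.21 and -0.09, clock genes by 0.15 and -0.04, pericentral genes by -0.17 and -0.31, and periportal genes by -0.10 and -0.24. Kupffer cell genes differed by 0.02 and -0.04, stellate cell genes by -0.01 and 0.24, and adipocyte genes by 0.36 and -0.75.

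For MET_KO_canertinib against the other 3 arms, fatty acid oxidation genes differed by -0.46 at 4 of 4 days, with an exact permutation p of 0.00781, an adjusted p of 0.155 and a value of -0.64 with the array set as a term. Neutrophil genes differed by 1.08 at 4 of 4 days (exact permutation p = 0.0195, adjusted 0.194, 1.07 with the term) and cytokines by 0.61 (exact permutation p = 0.0117, adjusted 0.193). The day 14 array of MET_KO_canertinib carries much of this, with day 14 differences of 1.91, 1.001 and -0.81 for neutrophil, cytokine and fatty acid oxidation genes. Of the camera calls in the 12 comparisons, that of the S phase list for the day 2 response alone held with an estimated correlation. Its p-value was adjusted over the lists of that comparison and not over the 12 comparisons. It also rests on 1 day 2 array of MET_KO_canertinib.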

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

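The tests of the array sets, of a loss of the drug difference at day 14, of RNA quality, of poly-A controls, of the splits that part every pair, of the spread between single arrays, of female animals and of exchanged genotype labels were chosen only after the result was seen. Those of hybridization controls, of a wrong day label and of other splits of the arrays were set before.

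The first pattern is the number of genes, 4699, that differed between the canertinib arms and the others. Against a loss of the drug difference at day 14, the day 14 arrays without canertinib lay at a mean of 0.913, beside 0.996 for the canertinib arrays of day 14, on an axis with the arms without the drug at 0 and the canertinib arms at 1 at days 0, 2 and 7. For array processing seen in spiked control transcripts, the hybridization controls differed by -0.419 (log2, high minus low set, exact rank p = 0.0727). The high set (9.922 to 11.26) lay inside the range of the low one (9.552 to 11.57), the overlap predicted if processing was not the cause. That low end is a single array, MET_KO at day 2, while the rest of the low set lay at 11.06 to 11.57. These controls therefore do not decide. RNA quality of the canertinib arrays is argued against as the source of most of the count, since in the knockout pair the log2 Gapdh 3' to 5' ratio differed by 0.477 at day 14 and by 0.129 at day 0, while the drug difference of 1000 genes predicted from other days had slopes of 0.0838 and 0.645 (in the flox pair 1.47 and 0.462, with slopes of 0.0819 and 0.611); it stays open for genes that differed at day 14. A difference between the array sets may make up most of the count, since over both genotypes the slope at day 14, within 1 set, was 0.0829 against 0.628, 0.938 and 0.679 at days 0, 2 and 7, and an effect of the drug at those days cannot be told apart from it, nor can labelling or background seen in poly-A controls, which differed by 0.924 (exact rank p = 0.00749) with 1 low-set array, at 5.07, inside the high range.

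The second pattern is the smaller day 2 change of cell cycle genes in MET_KO_canertinib, the arm in which Met was deleted and EGFR inhibited. A wrong day label could give it, since for 200 genes outside the cell cycle lists, chosen by their day 2 change in the other arms, the slope in this arm was 0.171, against 0.54, 0.772 and 0.518 in MET_FLOX, MET_KO and MET_FLOX_canertinib, and a weaker response to the operation would lower it as well. Low RNA quality stays open, as the mean correlation of 0.879 with the other arrays lay near the median of 0.873, while the Gapdh and actin 3' to 5' ratios of 1.35 and 1.94 were the highest of the 4 day 2 arrays (others up to 1.11 and 1.86). The spread between arrays of this arm and day was not measured, and 1 named arm of 4 is the lowest with a probability of 0.25 by chance. A blocked response to growth factors through both receptors is the biological explanation that the design names, and it remains a hypothesis that further day 2 arrays of each arm would test. The ERK-responsive score at day 2 was not lowest in MET_KO_canertinib. It was -0.332 in MET_FLOX, 0.127 in MET_KO, 0.201 in MET_FLOX_canertinib and 0.138 in MET_KO_canertinib, in single arrays of both array sets.

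The third pattern is Cyp17a1 and Mmd2, whose genotype by canertinib interactions of 4.99 and 6.56 mean that the genotype difference changed sign with the drug. Female animals in some arms are argued against by Y-linked genes, which differed by -0.0345 (95% interval -0.369 to 0.300) between the arms with high and with low Cyp17a1, while 2 Xist probe sets lay at 4 to 44 and the third at 229 to 1006, with a difference of -0.140 (-0.457 to 0.177). In each array 2 or 3 of the 3 Y-linked genes lay above the array median. Their levels moved with the array set, with Eif2s3y lower and Kdm5d higher in the high set. Kdm5d was under the array median in MET_FLOX at day 7 (123 against 174.7). On each diet both genotypes lie in the same array set at every day, so a set difference equal in both genotypes cancels in the interaction. The array sets are also argued against as the whole cause by the day 14 arrays, all of 1 set. There the interaction of Cyp17a1 was 3.77 (SE 1.24) and that of Mmd2 3.86 (SE 1.70), the latter only just beyond its 95% interval (lower bound 0.0192). Exchanged genotype labels in the arms without canertinib could give the same picture, as the genotype differences without and with the drug correlated at -0.147 across genes (-0.147 to -0.0919 without each day), the lowest value over all exchanges of labels within days (highest 0.147), yet too weak to decide, so the exchange and a true interaction cannot be told apart. Steroid and growth hormone state of the animals, which sets Cyp17a1 and Hsd3b5 in mouse liver, was not measured.

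Among 144 groups of 4 arrays, each the 4 days of 1 arm for 1 measure, 13 held an array far from the rest by its gap relative to the range. For equal draws chance gives about 1 in 20 groups, which is 7.2 here. The days of an arm form a time course and the lists are not independent, so 13 against 7.2 measures no excess. At day 2 the S phase score stood apart in MET_FLOX (1.42, the others from -0.492 to -0.228), MET_KO (1.76, from -0.547 to -0.461) and MET_FLOX_canertinib (1.06, from -0.396 to -0.199), and the G2/M score in MET_FLOX_canertinib (1.59, from -0.567 to -0.285). The score of hepatocyte transcription factors and secreted proteins was -0.483 in MET_FLOX at day 2 (others -0.0731 to -0.0319). The female-biased score was 0.668 in MET_FLOX at day 0 (others -0.0934 to 0.0185), the pericentral score 0.326 in MET_KO at day 7 (others -0.135 to -0.113) and the ER stress score 0.164 in MET_FLOX_canertinib at day 7 (others -0.1 to -0.0551). The MET_KO_canertinib day 14 array held 4 of the 13, with a bile acid score of -1.11 (others 0.0304 to 0.178), a fatty acid oxidation score of -1.13 (others -0.145 to -0.0215), a cytochrome P450 score of -1.15 (others -0.0163 to 0.184) and an array median of 265 (others 244 to 246.3). The actin 3' to 5' ratio was 1.88 in MET_KO at day 0 (others 1.36 to 1.41).

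Other splits of the same arrays into groups of the same sizes were counted, the real one included. For canertinib 1 of 100 gave as many, the real split (4699 genes, highest other 4127). The splits that also part the sets at days 0, 2 and 7 and exchange only day 14 arrays called 3939 and 4127. All the rest called at most 2, and they mix the array sets within a group, so the set difference counts as error. The counts thus follow the array sets, and the share of 1 in 100 does not exclude chance for the grouping by drug. For the interaction 3 of 100 gave as many, the real split (2 genes) and 2 that part the array sets. These called 3828 and 4594, the latter a split by canertinib. All other splits mix the array sets within an arm, so the set difference counts as error and can keep their counts low. The share of 3 in 100 therefore does not exclude chance for the interaction. For pairs of arms and of days only 8 of the 35 splits part every pair of arrays that share a day or an arm, too few for a share under 0.05. Over all 35 splits, 1 gave as many genes for MET_FLOX_canertinib against MET_FLOX (911, highest other 1), MET_KO_canertinib against MET_FLOX (391, highest other 0) and against MET_KO (1117, highest other 111), day 2 (52, highest other 3) and day 14 (11, highest other 10). As many came from 5 for MET_KO_canertinib against MET_FLOX_canertinib (1 gene, highest other 6) and 4 for day 7 (1 gene, highest other 2). A count of 0 is reached by every split, so the splits test nothing for the knockout arms (100 of 100, highest other 4699, a split by canertinib) and for MET_KO against MET_FLOX (35 of 35, highest other 7).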

How the results depend on the processing

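The fits with the array set as a term, fry, and the day 2 response against the mean of the other 3 arms were chosen only after the data were seen. The comparison of all knockout with all flox arms called 0 genes with limma under every setting run. For the shifts of counts below the cause was not tested; where arrays, days or arms are left out, fewer arrays remain.

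Quantile normalization gave 2808 genes for the canertinib arms, 372 for MET_FLOX_canertinib against MET_FLOX, 145 for MET_KO_canertinib against MET_FLOX, 310 for MET_KO_canertinib against MET_KO and 0 for MET_KO_canertinib against MET_FLOX_canertinib. Median centring gave 605 for MET_KO_canertinib against MET_FLOX, 45 at day 14 and 0 for MET_KO_canertinib against MET_FLOX_canertinib, which was also 0 with a pseudocount of 1, without a filter, with the mean of a gene's probe sets, with every probe set and with no intensity trend. Without a filter MET_KO_canertinib against MET_FLOX gave 241 and day 14 gave 6. A stricter filter gave 2900 for canertinib and 30 for day 2. The mean of a gene's probe sets gave 1 for the interaction, 0 at day 7 and 7 at day 14. With every probe set tested, the counts were 10026 for canertinib, 2557 for MET_FLOX_canertinib against MET_FLOX, 1060 and 2386 for MET_KO_canertinib against MET_FLOX and MET_KO, 4 for the interaction and 1 at day 14.

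With only the arms or days compared, MET_KO against MET_FLOX gave 1, MET_FLOX_canertinib against MET_FLOX 98, MET_KO_canertinib against MET_FLOX 1 and against MET_KO 3, day 7 gave 0 and day 14 gave 0. Without a block these were 24 for MET_FLOX_canertinib against MET_FLOX, 6 and 12 for MET_KO_canertinib against MET_FLOX and MET_KO, and 1 at day 14. Array weights gave 2 for MET_KO against MET_FLOX, 3643 for MET_FLOX_canertinib against MET_FLOX, 3179 and 3459 for MET_KO_canertinib against MET_FLOX and MET_KO, 6 for the interaction, 195, 3 and 838 at days 2, 7 and 14, and 3 for the day 2 response. Without an intensity trend the interaction gave 0, day 2 gave 28 and day 14 gave 1.

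With the array set as a term the counts were 15 for canertinib, 9 for MET_FLOX_canertinib against MET_FLOX, 5 and 10 for MET_KO_canertinib against MET_FLOX and MET_KO, and 27 at day 14. After quantile normalization the same term gave 47, 19, 18, 21 and 34 in that order. Without the MET_KO_canertinib day 14 array it gave 18, 25, 7 and 6, with 5 for the interaction and 123 at day 2. Against the mean of the other 3 arms the day 2 response gave 3 genes.

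No list passed by permutation by arm or by day, which the few allocations put out of reach of a single list. The smallest possible p by day, 0.003906, came to 0.129 after adjustment. By arm the smallest, 0.00154, came to 0.0764. The failure to pass thus does not show that lists were unchanged. Camera with the preset correlation called 19 list results for the canertinib and knockout contrasts and 34 by day, fry 7 and 6, camera with the array set as a term 17 and 35, and fry with it 4 by day. Across genes the correlation of the genotype differences was -0.106 without a filter.

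Leaving out each array, day or arm gave 595 to 6405 genes for canertinib, 0 to 2 for MET_KO against MET_FLOX, 0 to 3391 for MET_FLOX_canertinib against MET_FLOX, 0 to 2547 and 0 to 3593 for MET_KO_canertinib against MET_FLOX and MET_KO, 0 to 4 for MET_KO_canertinib against MET_FLOX_canertinib, 0 to 5 for the interaction, 0 to 189 at day 2, 0 to 5 at day 7, 0 to 152 at day 14, and 0 for the knockout arms and the day 2 response. At day 2 the count was 189 without the arm MET_KO_canertinib and 0 without any of the other arms.

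For the genes named in 93 genes and comparisons, 863 of 1061 values under the settings fixed before kept their direction and their side of the threshold, 197 no longer passed it, and 1 reversed, Cdc73 in MET_FLOX_canertinib against MET_FLOX, at -0.24 with a pseudocount of 1. Of 1860 values with arrays, days or arms left out, 1103 kept both and 757 no longer passed. Of 279 with the array set as a term 65 kept both, 210 no longer passed and 4 reversed. These were, without the MET_KO_canertinib day 14 array, Dus2 at -0.16 for canertinib, -0.71 for MET_KO_canertinib against MET_FLOX and -0.59 against MET_KO, and Dnajc16 at 0.0918 against MET_KO. Signals near background limit such fold changes, since a pseudocount of 16 and one of 1 differ most there.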

Other observations

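The genes named in this part were chosen only after their values were seen; the tests of list scores by day were set before. In MET_KO at day 0 the male-biased score was 1.37, the highest of the 16 arrays. Hsd3b5 gave 12599 there against 54 in MET_FLOX, 1209 in MET_FLOX_canertinib and 16 in MET_KO_canertinib, and Elovl3, a fatty acid elongase that is higher in male liver, gave 17681 against 931, 6625 and 1167. Cyp4a12a, a male-specific hydroxylase, gave 18662 against 3849, 13001 and 5098. For the interaction the male-biased list had a mean of -1.50, with 0 genes called and 4 of 12 lower and 1 higher when adjusted over the list alone (adjusted p = 0.556 with an estimated correlation). Cyp7b1, a member that went the other way, had an interaction of 2.37 (SE 0.57). Igfbp2, a binding protein of insulin-like growth factors, had one of -2.75 (SE 0.55, adjusted p = 0.286), with 1368, 3109, 2515 and 1673 in MET_KO_canertinib and 9011, 12001, 8094 and 8668 in MET_KO at days 0, 2, 7 and 14.

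The metallothionein Mt1 varied more than 100 times between arrays, from 505 in MET_KO at day 0 to 74344 in MET_KO_canertinib at day 14, and reached 52356 in MET_FLOX_canertinib at day 0 and 12436 in MET_FLOX at day 7. S100a8, a neutrophil alarmin, gave 22731 in MET_KO_canertinib at day 14 and 4349 at day 2, and at most 1114 in the other arms. Saa3 gave 25464 and 9966 in the same arrays. Ehhadh, the peroxisomal enzyme, gave 225 in MET_KO_canertinib at day 14 and 17403 at day 7. Tubb6, a tubulin that follows cell division, gave 1554, 2088 and 1349 at day 2 in MET_FLOX, MET_KO and MET_FLOX_canertinib and 24 in MET_KO_canertinib. The heat shock gene Hspa1b gave 5192, 7946, 2151 and 1796 at day 7 in the 4 arms, in the order MET_FLOX, MET_KO, MET_FLOX_canertinib and MET_KO_canertinib.

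Cholesterol synthesis scores were lowest at day 7 with canertinib, at -1.55 in MET_FLOX_canertinib and -0.95 in MET_KO_canertinib, and 0.72 and 0.03 in MET_FLOX and MET_KO. The score of day 7 differed from the other days by -0.58 in 3 of 4 arms (exact permutation p = 0.0469, adjusted 0.326). Stellate cell and matrix genes had a score of -0.44 at day 0 relative to the other days, in 4 of 4 arms, at an exact permutation p of 0.003906, the smallest these permutations can give (adjusted 0.129). The list of MET and EGFR ligands, receptors and adaptors differed by -0.25 at day 2 in 4 of 4 arms (exact permutation p = 0.00781, adjusted 0.147), with 0 of 21 genes called and 2 lower when adjusted over the list alone. Erythroid and acinar genes differed by 0.63 and 0.42 at day 14 (exact permutation p = 0.00781 for both), where the arms without canertinib change array set.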
